A study of Mus musculus with 4 samples.

How the data were processed

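RNA of whole ear skin was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, which read each transcript with probes along its length, per the labels' protocols. The 4 arrays form 4 groups of 1: f/f untreated, f/f IMQ, EKO untreated and EKO IMQ, assigned from the sample titles. The deposited values are log2 probe set levels made with RMA, a method of background correction, quantile normalization and probe summarisation, per the submitters' processing notes. The version and annotation used are not given in the sources used here. The log2 scale was read from the deposited values, which run from 2.58 to 13.8 with array medians of 6.57, 6.52, 6.54 and 6.53. The 4 distributions were alike but not identical, the largest gap between quantiles being 0.174. RMA draws probe effects from all arrays at once and equalises their distributions, so a shift of most genes in one direction would be hidden, and low signals are compressed toward background.

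Gene names came from the platform annotation supplied with the data. Of 35556 probe sets, 21789 were listed with 1 gene symbol, 1621 with several and 12146 were not listed; only the first kind was used and named. Symbols were checked by Entrez identifier against RefSeq gene names of assembly GRCm38.p6, used for names alone, where 21698 of these probe sets were found and 0 symbols differed. The probe set with the highest mean over the 4 arrays stood for each of 19938 genes, 999 of which had several. No genomic position is given because none was paired with the probe sets in the sources used here.

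Log2 differences were computed for 5 comparisons: IMQ in f/f, IMQ in EKO, EKO against f/f untreated, EKO against f/f with IMQ, and the difference of the IMQ differences. A gene was counted when its difference was at least 1 (2-fold) and its level reached the median of all named genes on at least 1 array of the comparison. This floor lay between 6.93 and 6.98. The named genes are the 10 largest in each direction (5 for untreated EKO against f/f) among these, leaving out gene models without an established name, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments. Also named are Traf6, the 5 genes per direction with the smallest adjusted p in each averaged test, and up to 4 leading members per list plus members that a sentence on the list needs. Il36a, Il36b and Il36g appear in the annotation under older symbols.

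The 31 gene lists, the comparisons, the naming rule and the alternatives were fixed before the data were examined. A list's median difference was placed among 10000 random lists of the same size, matched on mean level in 20 bins, and is said to stand apart at a percentile of at least 97.5 or at most 2.5; lists under 5 measured members received none. If genes varied independently, chance would place 1.5 of 30 lists apart. Members of a list can vary together from ear to ear and lists share members, so more can stand apart by chance. In f/f with IMQ, 10 stood apart as higher and 8 as lower; in EKO 10 and 7; without IMQ 7 and 10; with IMQ 7 and 13; and for the difference of differences 10 and 10. These percentiles describe the arrays and are not tests of the conditions.

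Effects averaged over the other factor were fitted with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3 on 10646 genes that reached the floor on any array, with Benjamini-Hochberg adjustment and the other factor as covariate, 2 arrays per level. No group has a replicate array, so these p-values do not measure a spread between like arrays or animals. They weigh an averaged effect against the genotype-by-IMQ difference plus noise, on 1 residual degree of freedom. Lists were tested with camera at a preset correlation of 0.01 and with an estimated one. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The limma step was tested on simulated data of the averaged IMQ effect over 10544 genes, where it recovered 72.0% of 50 genes changed 2-fold and 100% of those changed 4-, 8- and 16-fold, and called 6 of 10344 unchanged genes. Each simulated change was the same in both genotypes. This recovery therefore does not apply to genes whose IMQ difference depends on genotype. The list step placed 6.0% of 200 unchanged lists apart in simulated f/f data, where genes varied independently, and put a list shifted by 0.3 at percentile 100.

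Alternatives were other scalings between arrays (median, cyclic loess, quantile), no floor, the mean of a gene's probe sets, a 1.5-fold threshold, other list statistics, backgrounds and memberships, and other limma settings. The orthogonal contrasts set the mean of 2 arrays against the mean of the other 2. Probe sets with several or no listed genes were left out of the comparisons, since no gene could be named from them.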

Results

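Expression was measured in whole ear skin of 8-week-old female mice on 4 arrays, each reading 35556 probe sets. The mice carried either an intact floxed Traf6 gene (Traf6f/f, here f/f) or an epithelial Traf6 knockout (Traf6EKO; here EKO stands for the arrays labelled so). TRAF6 is an adaptor and ubiquitin ligase that passes signals from Toll-like receptors and from the IL-1 and IL-17 receptor families to NF-kB and MAP kinases. Ears were left untreated or received a cream with imiquimod (IMQ), a TLR7 agonist used to provoke psoriasis-like inflammation in mouse skin, at 10 mg per day for 2 days. Each of the 4 groups holds 1 array, so no value below has a replicate error, and differences between pairs of arrays carry no p-value. The series' description gives n = 2, and whether RNA of 2 mice was pooled on each array is not given in the sources used here. The comparisons ask how skin responded to IMQ in each genotype, and how the genotypes differed without and with IMQ. The number of arrays limits the precision. Differences and list medians below are log2 values unless they are given as folds. Array medians lay between 6.52 and 6.57 (log2), and correlations across probe sets, which are not independent replicates, were between 0.981 (f/f untreated with f/f IMQ) and 0.995 (f/f untreated with EKO untreated).

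Traf6 itself, read by 1 probe set, was not lower on the arrays labelled EKO. Its level was 9.51 in f/f untreated, 9.30 in f/f IMQ, 9.65 in EKO untreated and 9.35 in EKO IMQ skin, so that EKO was higher by 0.14 (log2) without IMQ and by 0.05 with IMQ. Whole ear also holds cells outside the epithelium, and where the probes lie relative to the deleted part is not given in the sources used here, so this level does not check the labels. Every genotype difference below is between arrays labelled EKO and arrays labelled f/f. The list of 32 measured receptors, adaptors and kinases around TRAF6 lay within the range of random lists in all 5 comparisons, with medians of 0.01 (IMQ in f/f), 0.04 (IMQ in EKO), 0.02 (EKO against f/f untreated), -0.03 (EKO against f/f with IMQ) and -0.03 (difference of the IMQ differences). Myd88, an adaptor upstream of TRAF6, was higher with IMQ by 0.98 in f/f and by 0.27 in EKO.

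**Figure D1:**
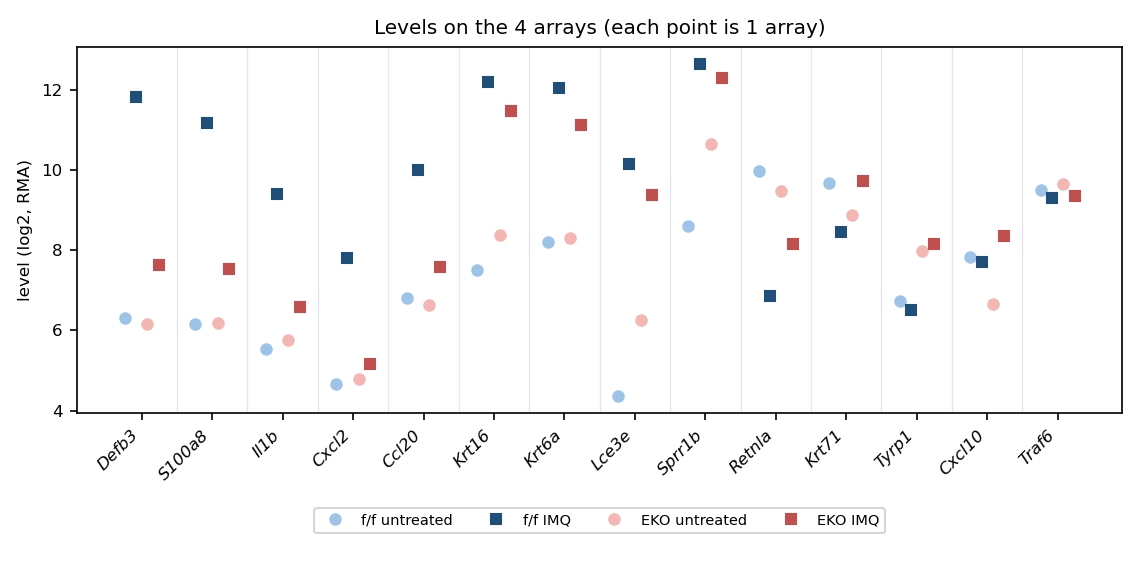
Level (log2, RMA) of 14 genes on the 4 arrays, each point being 1 array and the genes being picked for display after their values were seen. Defb3 stood at 11.84 in f/f IMQ and 7.64 in EKO IMQ skin, while Krt16 stood at 12.20 and 11.47.

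In f/f skin, stress keratinocyte, cell cycle and IL-17-responsive genes were higher with IMQ. Of 10548 genes above the floor, 403 were at least 2-fold higher and 277 at least 2-fold lower with IMQ. The largest difference was in Lce3e, a late cornified envelope gene, at 55.7-fold, followed by the beta-defensin Defb3 (46.0-fold), the calprotectin subunits S100a8 (32.2-fold) and S100a9 (26.7-fold), and the wound keratin Krt16 (25.8-fold). Lce3a (24.7-fold), the beta-defensin Defb4 (23.6-fold), the small proline-rich genes Sprr2e (23.1-fold) and Sprr2g (21.5-fold), and the cystatin gene Csta3 (18.5-fold) completed the 10 largest. Among genes lower with IMQ, Retnla, a gene of alternatively activated macrophages, led at 8.73-fold, followed by Serpina3b (6.92-fold), the cytochrome P450 gene Cyp2e1 (6.40-fold), Krtap6-1 (6.06-fold), Inmt (5.74-fold), the C-type lectin Cd209a (5.37-fold), Scgb1a1 (4.96-fold), Ces1d (4.70-fold), the desaturase Scd3 (4.47-fold) and Mylk4 (4.40-fold). Of these higher genes all but Krt16 lay below the floor of 6.98 in untreated f/f skin, and of the lower genes all but Cyp2e1, Cd209a, Ces1d and Scd3 lay below it (6.93) with IMQ. Signal there approaches background, so these folds and their order are imprecise. Sprr2, Lce3, Defb, Stfa and Krtap genes have near-identical relatives, and probe sets may read more than their own gene.

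Of the 33 measured stress and hyperproliferative keratinocyte genes, all were higher with IMQ in f/f and 21 at least 2-fold, with a 6.07-fold median that lay above all 10000 level-matched random lists. Krt6a was higher by 3.85, Krt6b by 3.43, and the gap junction gene Gjb2 by 3.48. All 35 cell cycle genes were higher, 28 of them at least 2-fold (median 1.43, above all 10000 random lists), including Bub1 (2.41), Plk1 (2.30) and Mki67 (1.91). Terminal differentiation genes showed a smaller median of 0.31 (percentile 99.7), with 3 of 31 at least 2-fold higher, among them Tgm3 (1.62) and Casp14 (1.58), while Flg2 (-0.99) and Krt77 (-0.94) were lower. Basal keratinocyte genes did not stand apart (median 0.09, percentile 63.0), although Krt15, a basal keratin, was at -1.94 and Cdh3 at 1.35. Of 19 wound and tissue-protease genes, 18 were higher and 8 at least 2-fold (median 0.76, above all 10000 random lists), with the kallikreins Klk6 (3.48) and Klk13 (3.47) and the protease inhibitor Timp1 (2.46).

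Several lists of inflammatory genes were also higher with IMQ in f/f skin. IL-17-responsive epithelial genes had a median of 1.17, above all 10000 random lists, and 17 of 30 were at least 2-fold higher. Besides the defensins and calprotectin genes they included Saa3 (3.92), the chemokine Ccl20 (3.19), Cxcl2 (3.15) and Slpi (2.97). Neutrophil markers, which share S100a8 and S100a9 with that list, had a median of 0.91 (above all 10000 random lists) with 11 of 25 at least 2-fold higher, including Stfa3 (3.90), Trem1 (2.86) and Clec4e (2.58). Granule genes on the same list differed little, with Elane at -0.04 and Ltf at 0.15. Neutrophil chemoattractants stood above all 10000 random lists (median 0.69), with Il1b at 3.88, Cxcl2 at 3.15 and Ccl3 at 2.81 among 3 of 11 at least 2-fold higher. NF-kB target and feedback genes likewise lay above all 10000 random lists (median 0.53, 6 of 23 at least 2-fold higher), with Ptgs2 (3.23), the prostaglandin synthase gene, and Bcl3 (2.26). IL-23/IL-17 axis genes had a median of 0.42 (above all 10000 random lists), where Il1b (3.88) and Il1a (2.04) passed 2-fold while Il23a (0.82), Il17f (0.53) and Il17a (0.31) did not and remained below the floor. That list no longer stood apart when members shared with other lists were left out. Interferon-stimulated genes had a median of 0.22 (percentile 99.8) with 0 of 33 past 2-fold, the largest being Oas3 (0.95) and Oas1a (0.79). Chemokines for monocytes, dendritic cells and T cells (median 0.10, percentile 92.0) and interferon-gamma-type genes (median -0.11, percentile 13.7) did not stand apart, although Ccl7 (1.77) and Ccl2 (1.75) were at least 2-fold higher and the chemokine list stood apart by the mean (0.35).

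Genes of other tissue layers were lower with IMQ in f/f. All 36 skeletal muscle genes were lower, 11 at least 2-fold (median -0.86, below all 10000 random lists), including Actn3 (-1.53) and Myoz1 (-1.51). Adipocyte genes were lower at a median of 2.00-fold (below all 10000 random lists) with 10 of 20 at least 2-fold lower, among them Thrsp (-2.04), Lep (-2.02) and Adipoq (-1.94). Hair follicle and hair shaft genes had a median of -0.67 (below all 10000 random lists), 11 of 31 being at least 2-fold lower. Smaller negative medians were seen for cartilage genes (-0.38, percentile 0.01), mast cell markers (-0.44, percentile 0), fibroblast and matrix genes (-0.25, percentile 0.12) and endothelial genes (-0.26, percentile 0.69). The fibroblast and endothelial lists no longer stood apart by the mean, with Timp1 (2.46) and Mmp3 (0.98) higher among the fibroblast genes. Macrophage markers (median -0.16, percentile 2.81), dendritic cell markers (-0.12, above 299 of 10000 random lists), nerve genes (-0.17, percentile 6.23), melanocyte genes (-0.15, percentile 4.58), sebaceous genes (0.18, percentile 94.5), T cell markers (-0.00, percentile 60.4) and B cell markers (0.02, percentile 69.7) lay within the random range. Some of these depended on the setting: dendritic cell markers stood apart as lower by the mean (-0.26), with members above the floor only (-0.82) and against random lists not matched on level. Macrophage markers did so with members above the floor only (-0.22) and without matching, nerve genes with members above the floor only (-0.41), and sebaceous genes stood apart as higher without matching. Of 11 erythroid genes only 3 were measured, too few for a percentile: Alas2 was at 0.29, Slc4a1 at 0.00 and Bpgm at -0.41.

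In EKO skin, stress keratinocyte and cell cycle genes were again higher with IMQ, at smaller folds. Of 10285 genes above the floor, 69 were at least 2-fold higher and 10 at least 2-fold lower. Lce3e was 8.65-fold higher and Krt16 8.50-fold, followed by Spink7 (7.03-fold), Krt6a (7.02-fold), the cornified envelope gene Rptn (6.97-fold), Stfa3 (6.01-fold), Krt6b (5.13-fold), the lactoperoxidase gene Lpo (4.70-fold), Gsta4 (4.26-fold) and Stfa2 (4.05-fold). The 10 lower genes were Serpina3b (3.67-fold), Cd209a (2.53-fold), Retnla (2.48-fold), Mgl2 (2.23-fold), Cd209d (2.15-fold), Lep (2.14-fold), Abca5 (2.13-fold), Scgb1a1 (2.12-fold), Trim12a (2.08-fold) and Ppil6 (2.04-fold). Lce3e, Spink7, Rptn, Lpo and Stfa2 lay below the floor in untreated EKO skin, and Serpina3b, Lep, Scgb1a1, Trim12a and Ppil6 below it with IMQ, so their folds are imprecise. Untreated levels of Lce3e and Krt16 were 6.27 and 8.38 in EKO against 4.36 and 7.51 in f/f, which lowers their EKO folds.

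Stress keratinocyte genes had a median of 0.87 in EKO, with 12 of 33 at least 2-fold higher, and cell cycle genes a median of 0.76, with all 35 higher and 4 at least 2-fold; each lay above all 10000 random lists. IL-17-responsive epithelial genes had a median of 0.35 (above all 10000 random lists), 4 of 30 being at least 2-fold higher, namely Saa3 (3.33-fold), Defb3 (2.78-fold), S100a9 (2.58-fold) and S100a8 (2.56-fold). Neutrophil markers had a median of 0.19, above all 10000 random lists, with 19 of 25 higher and 6 lower. The 5 at least 2-fold higher included Stfa3, Stfa2, S100a9 and S100a8, the last 2 being also on the IL-17-responsive epithelial list. The myeloid receptor gene Trem1 stayed below the floor in EKO, at 4.57 untreated and 4.72 with IMQ. Wound genes had a median of 0.13 (percentile 99.9). Neutrophil chemoattractants (0.02, percentile 76.7), IL-23/IL-17 axis genes (0.01, percentile 62.9), NF-kB targets (0.05, percentile 95.2), interferon-stimulated genes (-0.05, above 1995 of 10000 random lists) and interferon-gamma-type genes (-0.03, percentile 48.1) lay within the random range. NF-kB targets, however, stood apart as higher by the mean (0.13), with members above the floor only (0.14) and after cyclic loess (0.08), and neutrophil chemoattractants did so by the mean (0.18). Monocyte, dendritic cell and T cell chemokines had a median of 0.11 (percentile 99.8), which became -0.02 when members shared with other lists were left out. Sebaceous genes (0.16, percentile 99.9) and terminal differentiation genes (0.17, percentile 100) were higher, and hair shaft genes had a median of 0.50, above all 10000 random lists. Muscle genes (-0.32), adipocyte genes (-0.30), cartilage genes (-0.28) and fibroblast genes (-0.23) were each below all 10000 random lists.

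The IMQ differences of the genotypes, which share no array, ran in parallel across 10646 genes (Pearson r = 0.798, Spearman rho = 0.794, across genes, which are not independent replicates), with a slope of 0.380 for EKO on f/f, 1.68 for f/f on EKO, and an SD ratio (EKO over f/f) of 0.476. Noise shrinks each slope. Of the 403 genes at least 2-fold higher in f/f, 399 were above 0 in EKO, 62 reached 2-fold there, and 401 had the smaller difference in EKO, with medians of 1.40 in f/f and 0.66 in EKO. Over the 10187 genes above the floor in both comparisons, independent lists would share 2.73 genes. Choosing genes by their f/f value inflates that value, so the reverse choice was made as well: among the 69 genes at least 2-fold higher in EKO, the median was 1.36 in EKO and 2.43 in f/f, and 60 had the smaller difference in EKO. For the 277 genes lower in f/f the medians were -1.23 and -0.44, 233 of them were below 0 in EKO, and all 10 genes lower in EKO were among them. The 7 genes at least 2-fold higher in EKO but not in f/f, named after their values were seen, were the chemokine Cxcl10 (-0.11 in f/f, 1.70 in EKO), Pinlyp, Tchh and the keratin-associated genes Krtap19-1, Krtap21-1, Krtap24-1 and Krtap8-1. Among list members at least 2-fold higher in f/f, the median fraction of the f/f difference seen in EKO was 0.516 for 28 cell cycle genes, 0.432 for 21 stress keratinocyte genes, and 0.271 both for 17 IL-17-responsive genes and for 11 neutrophil markers. The IL-17-responsive and neutrophil lists share S100a8 and S100a9, so their equal fractions are not separate results.

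**Figure D2:**
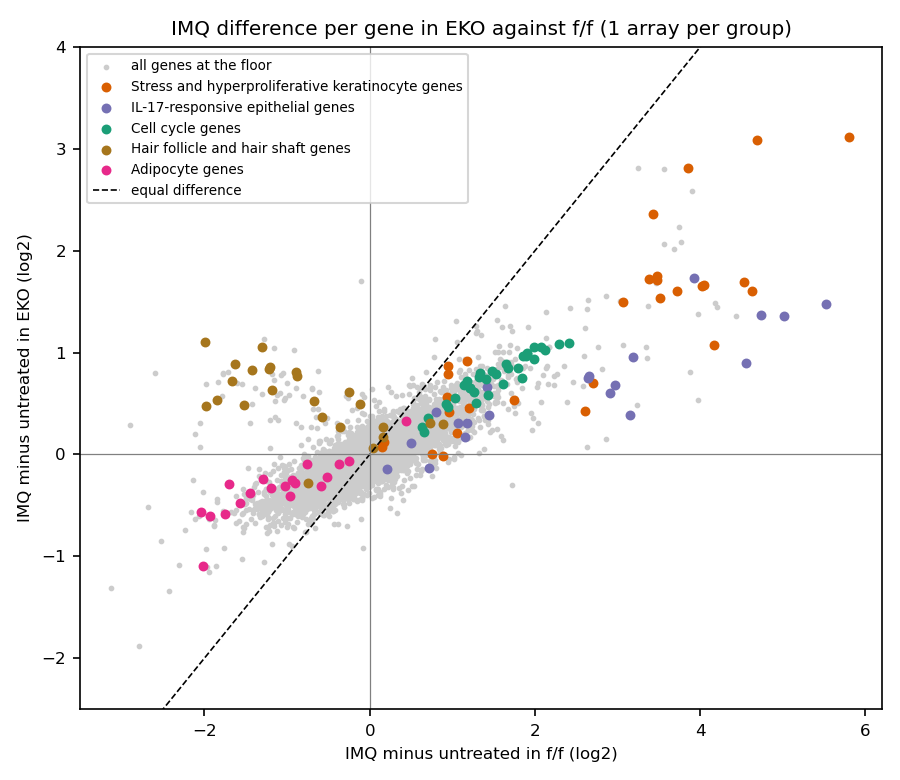
IMQ minus untreated level per gene (log2) in EKO (vertical axis) against f/f (horizontal axis), for 10646 genes above the floor, with members of 5 lists coloured and the dashed line marking equal differences. Most genes higher in f/f lie below the dashed line, and hair shaft genes lie in the upper left.

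Taking the difference of the IMQ differences, 113 genes were at least 2-fold higher and 126 at least 2-fold lower in EKO than in f/f. The lower genes were led by Defb3 (16.5-fold), Defb4 (12.7-fold), S100a8 (12.6-fold), Sprr2j-ps (10.8-fold), S100a9 (10.3-fold), Sprr2f (8.50-fold), Il1b (8.39-fold), Sprr2g (8.38-fold), Lce3a (8.13-fold) and Sprr2e (7.16-fold). The higher genes were led by hair genes: Krtap6-1 (10.6-fold), Krtap8-1 (8.54-fold), Krtap7-1 (5.95-fold), Krtap4-16 (5.93-fold), Krtap6-3 (5.85-fold), Krtap6-5 (5.73-fold), Krt33a (5.71-fold), Krtap3-3 (5.49-fold), Krtap21-1 (5.34-fold) and Gprc5d (5.23-fold). All 10 lower genes were below the floor on both untreated arrays, and Krtap6-1, Krtap6-3, Krtap6-5, Krtap21-1 and Gprc5d were below it in f/f IMQ skin, so these folds are imprecise. List medians of this difference were -1.22 for stress keratinocyte genes (33 of 33 lower), -1.01 for IL-17-responsive genes (26 of 30 lower), -0.76 for neutrophil markers (20 of 25 lower), -0.75 for wound genes (18 of 19 lower), -0.74 for cell cycle genes (35 of 35 lower), -0.68 for neutrophil chemoattractants (10 of 11 lower) and -0.49 for NF-kB targets (21 of 23 lower), each below all 10000 random lists. Hair shaft genes (0.94, 27 of 31 higher), adipocyte genes (0.70, 18 of 20 higher) and muscle genes (0.51, 33 of 36 higher) lay above all 10000. Untreated levels enter these values: stress keratinocyte and cell cycle genes were already higher in untreated EKO than in untreated f/f skin (medians 0.27 and 0.46). With 1 array per group this difference was not tested.

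**Figure D3:**
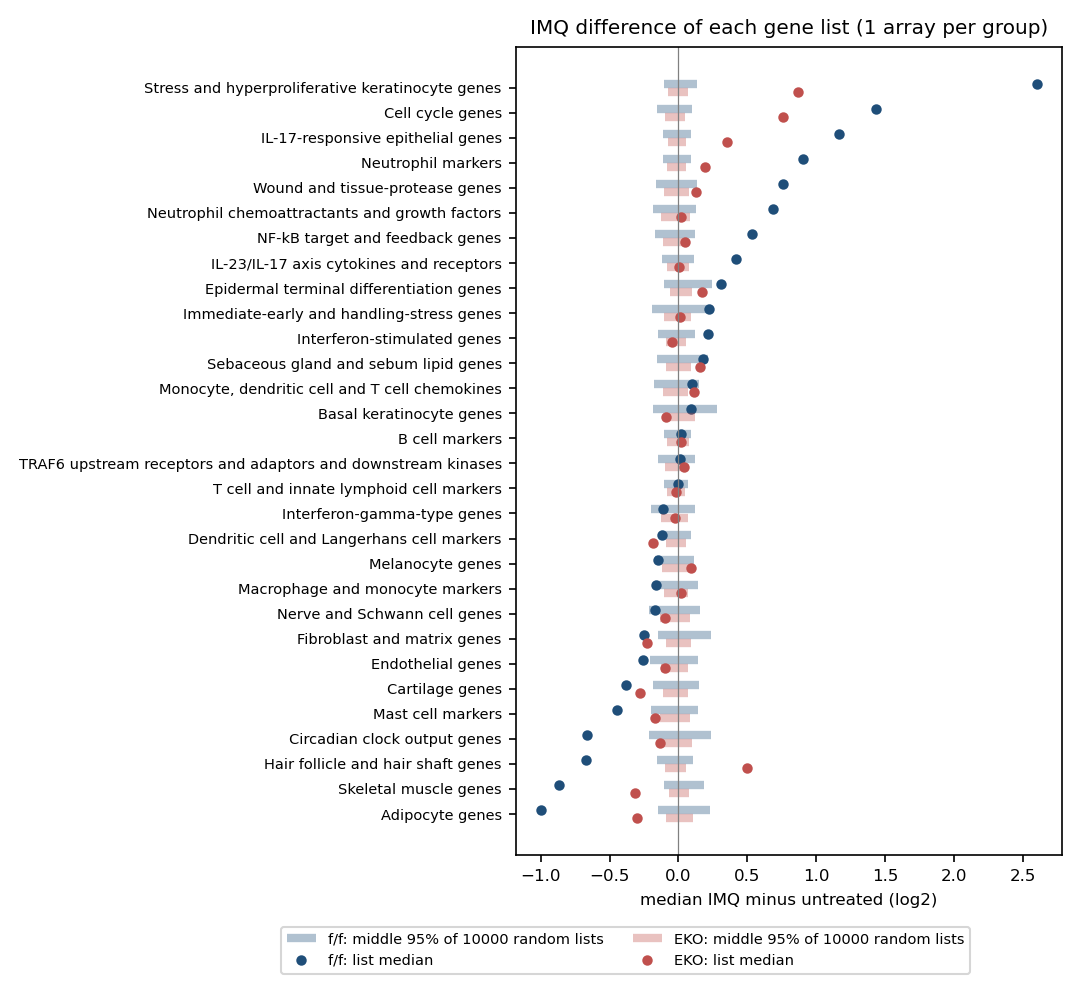
Median IMQ minus untreated difference (log2) of 30 gene lists in f/f (blue) and EKO (red); points are list medians and bars the middle 95% of 10000 random lists of the same size matched on level. Cell cycle genes stand at 1.43 in f/f and 0.76 in EKO, and hair shaft genes at -0.67 and 0.50.

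Without IMQ, EKO and f/f skin differed in few genes: of 10200 above the floor, 7 were at least 2-fold higher in EKO and 33 at least 2-fold lower. The 5 largest higher in EKO were Sprr1b (4.09-fold), Lce3c (2.76-fold), the melanin synthesis gene Tyrp1 (2.38-fold), Aox4 (2.30-fold) and Ptgs2 (2.26-fold). The 5 largest lower were Krtap6-3 (4.05-fold), Scd3 (3.79-fold), the hair gene Prr9 (3.15-fold), Krtap4-16 (3.04-fold) and the interferon-gamma-induced chemokine Cxcl9 (2.80-fold). Tyrp1 and Ptgs2 in f/f and Krtap6-3 in EKO lay below the floor, so their folds are imprecise. All 35 cell cycle genes were higher in EKO at a median of 0.46, with 0 past 2-fold, including Ccna2 (0.82) and Plk1 (0.82). Terminal differentiation genes (median 0.31, 30 of 31 higher) and stress keratinocyte genes (0.27, 26 of 33 higher) also lay above all 10000 random lists, and basal keratinocyte genes stood at 0.16 (percentile 99.2), though not by the mean. IL-17-responsive genes (0.00, percentile 59.6), neutrophil markers (-0.02, percentile 34.4) and NF-kB targets (0.02, percentile 65.3) lay within the random range. With members above the floor only, IL-17-responsive genes stood apart as higher in EKO (0.31), and NF-kB targets did so by the mean (0.08). Hair shaft genes (-0.67, 24 of 31 lower), adipocyte genes (-0.44, 18 of 20 lower), sebaceous genes (-0.40, 20 of 24 lower), endothelial genes (-0.20, 20 of 20 lower), macrophage markers (-0.18, 23 of 25 lower), muscle genes (-0.14, 31 of 36 lower) and fibroblast genes (-0.10, 23 of 25 lower) were each below the middle 95% of random lists. Mast cell markers had a median of -0.19 with 12 of 13 lower. The untreated f/f array also enters the IMQ comparison in f/f, so chance values of that array move both the same way.

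With IMQ, EKO skin had lower levels of IL-17-responsive genes, neutrophil markers and stress keratinocyte genes than f/f skin. Of 10282 genes above the floor, 90 were at least 2-fold lower and 43 at least 2-fold higher in EKO. The largest were Defb3 (18.3-fold lower), S100a8 (12.5-fold), Sprr2j-ps (12.3-fold), Defb4 (11.5-fold), S100a9 (10.6-fold), Sprr2f (8.07-fold), the cytokine gene Il1b (7.12-fold), Sprr2e (6.97-fold), the myeloid receptor gene Trem1 (6.48-fold) and Lce3a (6.29-fold). Higher in EKO were Krtap19-1 (5.35-fold), Krtap8-1 (4.62-fold), Scgb1b27 (4.61-fold), Krtap19-5 (4.30-fold), Car6 (4.28-fold), Krtap15 (4.22-fold), Krtap6-1 (4.17-fold), Krtap19-3 (3.88-fold), Krtap7-1 (3.25-fold) and Krt33a (3.20-fold). Sprr2j-ps, Defb4, Sprr2f, Il1b and Trem1 lay below the floor in EKO IMQ skin, and Krtap19-1, Krtap19-5, Car6, Krtap6-1 and Krtap19-3 below it in f/f IMQ skin, so these folds and their order are imprecise. Not every small proline-rich gene differed so much, Sprr1b being at -0.35. IL-17-responsive genes had a median of -0.99 (29 of 30 lower, 12 at least 2-fold), neutrophil markers of -0.78 (22 of 25 lower), stress keratinocyte genes of -0.73 (30 of 33 lower), neutrophil chemoattractants of -0.67 (10 of 11 lower), wound genes of -0.51 (18 of 19 lower), NF-kB targets of -0.46 (22 of 23 lower), monocyte, dendritic cell and T cell chemokines of -0.36 (16 of 20 lower), interferon-stimulated genes of -0.29 (27 of 33 lower), cell cycle genes of -0.27 (34 of 35 lower) and IL-23/IL-17 axis genes of -0.25 (15 of 19 lower), all below every random list. The IL-23/IL-17 axis call was lost with members of 1 list only and with members above the floor only. The chemokine list for monocytes, dendritic cells and T cells did not stand apart in the difference of the IMQ differences (-0.03, percentile 35.7). It was already lower in untreated EKO skin (-0.09, percentile 0.63), though not with members of 1 list only. Krt6b (-0.25), Krt16 (-0.73) and Krt6a (-0.92) differed by less than 2-fold. Terminal differentiation (0.22), melanocyte (0.35), muscle (0.38), adipocyte (0.27) and hair shaft genes (0.53) lay above all 10000 random lists, while T cell markers (0.00, percentile 76.7) and dendritic cell markers (0.01, percentile 77.3) lay within their range; T cell markers stood apart as higher with members above the floor only. This comparison shares an array with the IMQ comparison in f/f, so chance values of that array enter both.

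Averaged over genotypes, IMQ was also tested with limma, which leaves 1 residual degree of freedom and treats a genotype-specific IMQ difference as noise. No gene passed an adjusted p of 0.05: 0 were higher and 0 lower, 2808 of 10646 genes had an unadjusted p under 0.05 where chance gives 532.3, and the smallest adjusted p was 0.162. That adjusted p was shared by the top genes, including Spink7 (3.03 ± 0.16, SE), Rptn (3.18 ± 0.21), Krt6a (3.33 ± 0.28), Gadl1 (1.55 ± 0.10) and Slc13a3 (1.24 ± 0.10) among higher ones, and Serpina3b (-2.33 ± 0.24), Trim12a (-1.17 ± 0.15), the cartilage gene Cnmd (-1.04 ± 0.12), Pyy (-0.93 ± 0.09) and Ifitm6 (-0.77 ± 0.10) among lower ones. Adjusted over the list alone, 33 of 33 tested cell cycle genes, 23 of 29 stress keratinocyte genes, 7 of 13 wound genes and 6 of 14 neutrophil markers and 7 of 23 sebaceous genes rose, while 13 of 34 muscle genes, 12 of 19 adipocyte genes and 9 of 14 cartilage genes fell; 1 neutrophil marker fell and 1 adipocyte gene rose. Adjusted in the same way, 0 of 21 IL-17-responsive genes, 0 of 18 NF-kB targets and 0 of 31 terminal differentiation genes passed, and macrophage markers went both ways (4 of 22 rose, 3 fell). Camera with a preset correlation called 7 lists higher and 7 lower of 29 lists, led by cell cycle (adjusted p = 6.97e-17) and stress keratinocyte genes (adjusted p = 5.49e-14), with IL-17-responsive genes at an adjusted p of 2.6e-07 although none of them passed alone. With an estimated correlation camera called none (smallest adjusted p = 0.741). That estimate rests on 1 residual degree of freedom, so it cannot check the preset calls. The preset correlation takes genes as nearly independent, so its p-values can be too small.

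Averaged over treatments, the genotype difference by limma passed for 0 genes in either direction, with 344 of 10646 at an unadjusted p under 0.05 against 532.3 by chance and a smallest adjusted p of 0.999. Without the other factor in the model, 104 genes had an unadjusted p under 0.05, and with no floor 710 of 19938 did. Genes with the smallest p were the pigment genes Tyrp1 (1.45 ± 0.14, SE) and Dct (1.08 ± 0.16), Cyp17a1 (0.88 ± 0.12), Ndufa4l2 (0.80 ± 0.09) and Npbwr1 (0.65 ± 0.09), higher in EKO. Lower in EKO were Rnase2b (-1.42 ± 0.13), the sebaceous acyltransferase gene Dgat2l6 (-1.19 ± 0.10), Aadacl4 (-1.17 ± 0.13), Akr1c18 (-1.13 ± 0.10) and AAdacl4fm3 (-0.84 ± 0.11). Adjusted over the list alone, 9 of 23 sebaceous genes, 1 of 13 interferon-gamma-type genes and 1 of 19 adipocyte genes fell and 2 of 6 melanocyte genes rose; 0 of 31 terminal differentiation genes passed. Camera with a preset correlation called 7 lists higher and 13 lower, led by terminal differentiation genes (higher, adjusted p = 3.07e-12) and sebaceous genes (lower, adjusted p = 7.97e-11). With an estimated correlation camera called none (smallest adjusted p = 0.744). The limits of both settings given for the averaged IMQ effect hold here as well. On a common scale, the SD over genes was 0.403 for IMQ, 0.177 for genotype and 0.196 for their interaction, with 267, 34 and 57 genes at least 2-fold. Array noise enters these 3 values alike.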

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

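The tests of explanations in this part were chosen only after the results were seen, and the opposite movements below were not tested as differences, since each group holds 1 array. Hair follicle and hair shaft genes went opposite ways with IMQ, at a median of -0.67 in f/f and 0.50 in EKO. The same held for Krtap19-1 (-1.16 in f/f, 1.04 in EKO), Krtap21-1 (-1.28 and 1.14), Krtap8-1 (-1.99 and 1.10) and the follicle sheath gene Tchh (-1.30 and 1.06), and 34 of 35 Krtap genes above the floor were lower in f/f and higher in EKO. Scaling between arrays is argued against as the whole cause: scaling moves genes of the same level alike, but the list median of the difference of differences was 0.94 (quartiles 0.22 to 2.16), while the middle 95% of level-matched random lists lay between -0.11 and 0.09. That median was already known from the list results, so it is not a new check. After cyclic loess the list still stood apart in f/f, in EKO and in the difference of differences. Hair growth stage differing between the sampled mice may contribute, since the untreated arrays already differed by -0.67 in this list, but that value and the f/f value share the f/f untreated array, so a high hair level on it alone gives both, and with 1 array per group hair stage cannot be told apart from genotype. An effect of epithelial TRAF6 on follicles stays open and untested.

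The IMQ differences were smaller in EKO than in f/f. A compressed scale of the EKO arrays could contribute and cannot be told apart from genotype here: the SD over probe sets in EKO IMQ was 0.993 of that in f/f IMQ, but RMA brings this ratio near 1 whatever the cause. For IL-17-responsive genes, EKO IMQ stood at -0.99 against f/f IMQ. The untreated arrays differed there by 0.00, or by 0.31 with members above the floor only. On these arrays a higher untreated level was thus not the whole of it. For cell cycle genes, EKO IMQ stood at -0.27 and the untreated arrays differed by more, at 0.46. For stress keratinocyte genes, EKO IMQ stood at -0.73 and the untreated arrays differed by 0.27. Each of these values with IMQ lay below all random lists. On these arrays a higher untreated level was thus part of the smaller cell cycle and stress keratinocyte differences. With 1 array per group these values cannot be told apart from variation between ears, so whether genotype gave that untreated level stays open. Weaker exposure of the EKO ear to the cream may account for it: the fraction of the f/f difference was larger by 0.245 for cell cycle than for IL-17-responsive genes (quartiles 0.475 to 0.538 and 0.229 to 0.293), but genes can differ in dose response, and with 1 ear sample per group exposure and genotype cannot be told apart. The genotype itself, the biological explanation the design names, remains open.

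Muscle and adipocyte genes were lower with IMQ in f/f. Uniform dilution by thicker epidermis and infiltrating cells is argued against as the whole cause on this pair of arrays, since 53 muscle and adipocyte genes were lower than 41 fibroblast and endothelial genes by a median difference of -0.65, with quartiles of -1.19 to -0.66 and -0.43 to -0.07. However, 5 of 25 measured fibroblast genes and 3 of 20 endothelial genes were higher with IMQ, which can hide dilution there. These quartiles are over genes and give no spread between ears. Different amounts of muscle and fat in the dissected ears could also give it; the untreated ears differed by -0.14 in muscle genes and by -0.44 in adipocyte genes, the latter with 18 of 20 lower in EKO and below all 10000 random lists, but these values share the untreated f/f array with the f/f difference, and 1 pair of ears does not settle how much dissection varies, so it cannot be told apart from IMQ. A response of these tissues to IMQ stays open.

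Some probe sets outside the comparisons also differed with IMQ in f/f: of 778 above the floor and listed with several genes, 30 were at least 2-fold higher and 25 lower, and of 3851 with no listed gene, 52 were higher and 45 lower. Of 10548 named genes, 403 were higher and 277 lower, a larger share than among probe sets with no listed gene. The probe sets outside the comparisons cannot be named here, and their difference was not tested.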

How the results depend on the processing

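All alternatives here were planned. Counts at 2-fold stayed within 1.5 times under the other scalings, without a floor and with the mean of probe sets. At 1.5-fold the numbers higher and lower were 1074 and 1005 for IMQ in f/f, 274 and 83 for IMQ in EKO, 66 and 108 untreated, 209 and 268 with IMQ, and 389 and 493 for the difference of differences, as a lower threshold must give more. Genotype genes at an unadjusted p under 0.05 numbered 104 without the other factor and 710 with no floor, where more genes were tested; no setting gave a gene past the adjusted threshold. With an estimated correlation, camera called 0 lists higher and 0 lower for IMQ and 0 and 0 for genotype. That estimate rests on 1 residual degree of freedom, so it says little for or against the preset calls. With no floor, Spearman rho between the IMQ differences was 0.636, and the f/f median of genes higher in EKO was 2.62; the cause was not tested. The median of monocyte, dendritic cell and T cell chemokines with IMQ in EKO reversed to -0.0228 with members of 1 list only; the cause was not tested. Of 92 list results that stood apart, 76 did so under all alternatives and 16 were lost under at least 1. Over all list results and alternatives, 828 kept their side, 35 newly stood apart and 23 no longer did. The differences of the largest genes named for each comparison, but not those of other list members, were taken under 4 alternatives; 359 of these results kept direction and side of 2-fold, and 1 (Ppil6 in EKO) fell short of 2-fold under cyclic loess. Neutrophil chemoattractants have too few members of 1 list only for a value, and Traf6 has 1 probe set, so its alternative adds nothing. Within a genotype no paired analysis was possible because each group holds 1 array. The limma fit of IMQ, with genotype as covariate, set IMQ against untreated within each genotype. Signal near background limits genes below the floor, such as Il17a and Il23a.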

Other observations

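Clock output genes were lower with IMQ in f/f skin. Of 16 measured circadian genes, 14 were lower in f/f (median -0.67, below all 10000 random lists), and the median was -0.14 in EKO (percentile 1.20). The transcription factor genes Dbp (-0.95), Hlf (-0.99) and Tef (-0.80), the period genes Per3 (-1.02), Per1 (-0.72) and Per2 (-0.55), and the glucocorticoid-induced Tsc22d3 (-1.22) were lower in f/f, while Arntl (-0.12), Clock (0.24), Cry1 (-0.08) and Nfil3 (0.35) differed less. In untreated skin the list did not stand apart between genotypes (median 0.04, percentile 58.5), and with IMQ it was higher in EKO by 0.53. Time of sampling is not given in the sources used here.

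Some dendritic cell markers were lower with IMQ on both pairs of arrays: H2-Aa with differences of -0.96 in f/f and -0.62 in EKO, Cd74 by -0.84 and -0.55, and Mgl2 by -1.95 and -1.16, while Fscn1, a gene of mature dendritic cells, was higher by 1.60 and 0.92. The dendritic cell list had a median of -0.19 in EKO (percentile 0.01). Adjusted over the list alone, 6 of 12 of its tested genes fell and 2 rose when averaged over genotypes. Cd3g, a T cell receptor component, was at -1.24 and -0.77. The 28 measured T cell markers did not stand apart, with medians of -0.001 in f/f (13 higher) and -0.017 in EKO (12 higher). Immediate-early genes were higher in untreated EKO than in untreated f/f skin (median 0.29, 19 of 20 higher, above all 10000 random lists), with Fosb at 1.04 and Fos at 0.80, while with IMQ the list lay within the random range between genotypes (median -0.03, percentile 28.3). Their IMQ difference was 0.23 in f/f (17 of 20 higher, percentile 96.8; apart by the mean, without matching and after cyclic loess) and 0.01 in EKO, and the difference of differences was -0.44 (18 of 20 lower, below all 10000 random lists). This list also holds genes that answer to handling of the tissue. Interferon-gamma-type genes were lower in untreated EKO skin (median -0.22, 15 of 17 lower, below all 10000 random lists), with Cxcl9 at -1.48 and Iigp1 at -0.84. Melanocyte genes were higher in EKO without IMQ (median 0.16, percentile 100) and with it (0.35), led by Tyrp1 (1.25 and 1.65) and Dct (0.82 and 1.34).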
